A study of Homo sapiens with 654 samples.

How the data were processed

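Cell-free DNA (cfDNA), the short DNA fragments that dying cells release into blood, was taken from the serum of 654 people with lung cancer. The study's design text describes each sample as a separate patient. According to the sample descriptions, DNA came from 1.5 ml of serum and 10 ng of it was treated with bisulfite, which converts unmethylated cytosine and leaves methylated cytosine as it is. Padlock probes, single-stranded oligonucleotides that circularise around a target, then captured chosen regions of about 100 bp. The captured DNA was amplified to libraries of about 300 bp and read as 150 bp read pairs on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore and cutadapt 1.4.1 and aligned with Bowtie2 to the human genome build hg19. These upstream steps were not rerun here.

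The deposited values are methylation levels as a fraction from 0 to 1, per region and patient, with missing values marked, as the authors provided them. How CpG calls were combined into a region's level, and which read depth led to a missing value, is not given in the sources used here. No read counts accompany the fractions, so the depth behind each value is unknown, and no interval that needs read counts is given. The number of regions with a value per patient was used as the only measure of yield. An error that is large in regions of low depth would widen the spread between patients and weaken correlations, and this could not be separated from biological spread.

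The table has 888 regions. The 6 regions on the X chromosome were left out so that no patient's sex can be read from the values. A further 12 autosomal regions have no value in any patient. These 18 columns were not used, and 870 autosomal regions remain. Each region is named by its chromosome and a number. Multiplied by 100, the highest number on a chromosome reaches 0.762 to 1.015 times the end of that chromosome's last annotated gene over the 22 autosomes, with a median of 0.992. Numbers were therefore read as 100 bp bins, and positions below are given as chromosome and Mb on hg19 under that reading, which the table itself does not state. The gene ends used for this comparison belong to GRCh38, so it tests the scale and not the build. The names of 12 regions had been turned into calendar dates by spreadsheet software. Their levels were used, and they were left out of every distance, since chromosome and number can no longer be told apart. No annotation of hg19 was used here, so no gene or genomic context is given for a region. The planned results on gene groups and on promoter, exonic, intronic and intergenic regions were therefore not computed.

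Regions with a value in at least 80% of the patients were kept, which left 548 of 870. For each region the median, mean, SD, interquartile range and number of patients were computed. Regions were classed as low (median under 0.2), intermediate (0.2 to 0.8) or high (median over 0.8), which gave 240 low, 52 intermediate and 256 high regions. A region was called variable when its SD between patients was at least 0.1. For each patient the mean over low regions and the mean over high regions were taken over the regions with a value.

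Correlation between regions was computed on ranks taken within each region, over the patients with values in both regions, and is called Spearman rho below. Counts of pairs at or above 0.5 and at or below -0.5 were set against 100 shuffles of the patients within each region. Neighbouring regions were compared with regions on different chromosomes by a permutation test on region positions. There were 161 pairs of directly neighbouring bins and 164 pairs under 1 kb apart. Principal components were taken on standardised regions with missing values set to the region median, and the sign was set so that low regions have a positive mean loading. The low and high means were compared across patients by Pearson r and Spearman rho, again without the 2 patients farthest from the median of the low mean. Permutation tests were two-sided with 100000 resamples, for which 1e-05 is the smallest p. Tests of sample order and of alternative settings used 10000 resamples, for which 0.0001 is the smallest p. Bootstrap intervals cover 95% and resample patients 1000 times. Intervals of shares of patients are Wilson intervals at 95% and cover sampling of patients only.

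A test of each region against the mean deviation of the low regions was added after the data had been examined. It leaves out the region itself and all regions within 100 kb, and its p was adjusted by the Benjamini-Hochberg method over 548 regions with a threshold of 0.05. The summary of region pairs over 100 kb apart or on different chromosomes and the interquartile range per class were also added then.

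The named regions follow a rule set before the data were examined: the 5 highest and the 5 lowest medians, the 10 largest SDs, the 5 most positive and the 5 most negative loadings, and the 5 highest and the 5 lowest correlations between distant regions. Equal medians were ordered by the mean. Between 528 and 654 patients had a value in each named region. Neighbouring regions named outside this rule were chosen after their values were seen. The labels give a single group and no control samples, so no comparison between groups was possible. As a technical check the patients were divided into 4 consecutive blocks of sample numbers, whose meaning the labels do not give.

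Alternatives covered the filter on missing values, the class limits, the SD limit, the mean in place of the median, Pearson r in place of rho, residuals on each patient's mean methylation, logit and rank scales, a random division of the patients, and removal of extreme or poorly covered samples. The numbers of regions and of region pairs were planned as counts. Many are given as percents of the regions or pairs tested, a change of unit made after the data had been examined. Whether an alternative moved such a result was still judged on its count, as a change by more than 1.5 times. In all, 120 alternatives were computed. The code was tested on simulated data with 548 regions. It found 50 of 50 planted region pairs and no pair at an absolute rho of 0.5 when nothing was planted. A planted axis gave 100 of 100 low and 100 of 100 high regions the planted direction, and 7 unplanted regions were called. With no axis planted, 0 regions were called. The planted pairs lacked the bounds and tied values of the data, and the planted axis shifted all its regions alike within a patient. Whether weaker effects would be found was therefore not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.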

Results

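The methylation of cfDNA was measured by bisulfite padlock capture in the serum of 654 patients with lung cancer, who form a single group. With a single group, the design asks how methylated each captured region is, how far patients differ, and which regions vary together. The median patient had a value in 75.7% of the 870 autosomal regions, with an interquartile range of 70.1% to 83.3% and a full range of 11.4% to 95.4%. The median region had a value in 91.9% of the patients. Read depth is unknown, so the precision of a single value cannot be stated. No pair of patients with enough values in common shared more than 3.05% of their values strictly between 0 and 1, so none of these was an exact copy of another. Samples with few values may not have been compared, and repeat libraries of the same patient would not be found in this way.

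Most of the regions measured in at least 80% of the patients had either a low or a high level in serum DNA. Of the regions with a value in at least 80% of the patients, 43.8% had a low median and 46.7% a high median. Only 9.49%, which is 52 regions, were intermediate. With class limits of 0.1 and 0.9 in place of 0.2 and 0.8, 20.3% were intermediate. The typical low region had a median level of 0.0170 (interquartile range 0 to 0.0489), the typical high region 0.9497 (0.923 to 0.969) and the typical intermediate region 0.577 (0.377 to 0.726). The bootstrap interval was 43.2% to 43.98% for low, 9.31% to 10.04% for intermediate and 46.5% to 46.7% for high regions. The filter on missing values left out 37.8% of all low, 45.8% of all intermediate and 34.02% of all high regions.

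A median of exactly 1 was found in 13 regions. Among these, the highest mean was at 120.6503 Mb on chromosome 12, with a level of 0.983 ± 0.0286 (SD) in the 86.4% of patients with a value. Next among them were the chromosome 6 region at 157.4304 Mb (mean 0.981), the chromosome 19 region at 46.0569 Mb (0.979), the chromosome 6 region at 157.4305 Mb (0.978) and the chromosome 11 region at 71.1851 Mb (0.976). Some regions with a median under 1 had higher means than the last 3 of these. A median of exactly 0 was found in 65 regions. Their lowest mean was that of the chromosome 10 region at 120.5149 Mb, with 0.00551 ± 0.0124 (SD) in the 85.3% of patients with a value. The chromosome 3 region at 150.3212 Mb had a mean of 0.00559. The adjacent chromosome 1 regions at 181.0580 and 181.0581 Mb had means of 0.00587 and 0.00629, and the chromosome 20 region at 30.3119 Mb had 0.00669. None of the patients reached a level of 0.5 in any of these 5 regions.

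**Figure D1:**
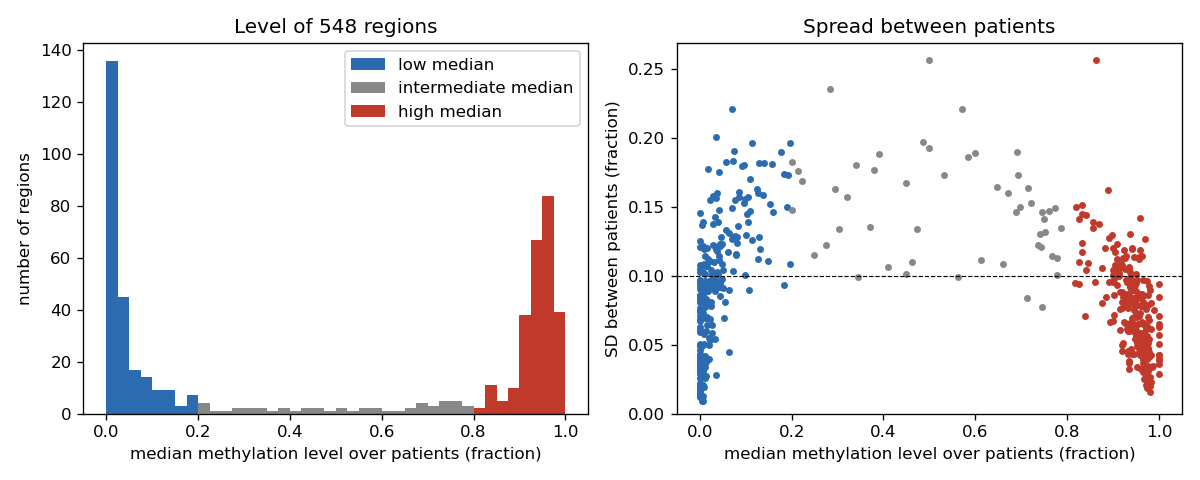
Levels and spread of the regions kept, in serum cfDNA. Left, number of regions by median methylation level (fraction) over patients, of which 43.8% were low, 9.49% intermediate and 46.7% high. Right, each point is a region, with its median level on the x axis and its SD between patients on the y axis; the dashed line marks an SD of 0.1, which 37.2% of the regions reached.

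The spread between patients was largest in the intermediate regions, while the order of low and high regions depended on the measure of spread. An SD of at least 0.1 was reached by 92.3% of the intermediate, 41.7% of the low and 21.9% of the high regions. The median SD was 0.147 in intermediate, 0.0922 in low and 0.0757 in high regions. The median interquartile range between patients was 0.192 in intermediate, 0.0451 in low and 0.0600 in high regions, so low regions had the larger SD and the smaller interquartile range. Without the 8 patients with a value in under 50% of the regions, the median SD of low regions exceeded that of high regions by 0.00579, against 0.0165 with them. In all, 37.2% of the regions were variable, with a bootstrap interval of 30.1% to 45.1%. When the scaled median absolute deviation replaced the SD at the same limit, 13.7% passed. The assay's own error could not be separated from this spread. The room that the scale leaves is also largest at intermediate levels, and the larger spread there could not be separated from that either.

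The largest SD was 0.256, at 75.5398 Mb on chromosome 17, where the median was 0.5 and 50.8% of the patients with a value had a level of at least 0.5. The next largest was found at 10.4872 Mb on chromosome 2, also 0.256 when rounded, around a median of 0.863, in the 85.3% of patients with a value. This chromosome 2 region had a rho of 0.121 with its directly neighbouring bin, against 0.547 for the chromosome 17 region at 75.5398 Mb with its own. Intermediate regions with a wide spread lay on chromosome 16 at 29.7573 Mb (median 0.283, SD 0.235) and on chromosome 17 at 57.9158 Mb (0.571, SD 0.220), 57.9157 Mb (0.5, SD 0.193) and 8.3700 Mb (0.487, SD 0.197).

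The other 4 of these 10 variable regions had a low median but a level of at least 0.5 in a minority of patients. On chromosome 20 at 37.4337 Mb the median was 0.0698, yet 9.58% of the patients with a value had a level of at least 0.5 (Wilson interval 7.38% to 12.3%). On chromosome 11 at 47.4165 Mb the median was 0.0357 and 6.10% reached 0.5 (4.38% to 8.44%). On chromosome 19 at 36.2334 Mb, with a median of 0.197, it was 10.3% of the patients (8.21% to 12.95%). On chromosome 1 at 151.1292 Mb, with a median of 0.113, it was 8.15% (6.25% to 10.6%). Their SDs were 0.221, 0.2003, 0.196 and 0.196, and a value was present in 83.03%, 82.7%, 97.6% and 95.7% of the patients.

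The largest component of variation between patients was one along which patients with more methylation in low regions had less in high regions. The first principal component held 17.4% of the variance of the standardised regions, against at most 0.691% in 100 shuffles. A positive loading was found in 94.2% of the low regions, and a negative loading in 94.1% of the high regions. Intermediate regions were divided, 28 positive and 24 negative. On ranks the component held 8.99%, and without scaling the regions it held 26.3%.

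The regions that weighed most on the positive side were low in the median patient. They lay on chromosome 7 at 45.0667 Mb (loading 0.0903, median level 0.0711), chromosome 11 at 70.2115 Mb (0.0880, level 0.126), chromosome 6 at 31.5278 Mb (0.0877, level 0.0738), chromosome 22 at 50.5241 Mb (0.0867, level 0.0633) and chromosome 10 at 118.8921 Mb (0.0862, level 0.129). A level of at least 0.5 was seen there in 3.70%, 5.22%, 6.62%, 2.91% and 3.22% of the patients. On the negative side were regions on chromosome 18 at 61.1439 Mb (loading -0.0910, median level 0.957), chromosome 22 at 45.5977 Mb (-0.0854, level 0.949), chromosome 1 at 3.2764 Mb (-0.0825, level 0.947), chromosome 2 at 74.1532 Mb (-0.0814, level 0.958) and chromosome 19 at 1.4964 Mb (-0.0808, level 0.935).

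The same opposition appeared in the class means. Patients with a higher mean over low regions had a lower mean over high regions, with Spearman rho -0.701 (bootstrap interval -0.746 to -0.651) and Pearson r -0.415 (-0.709 to -0.229), n = 654, and a permutation p of 1e-05 for both, the smallest possible. The median patient had a low mean of 0.0488 (interquartile range 0.0392 to 0.0655) and a high mean of 0.930 (0.921 to 0.938). Over all patients the low mean ran from 0.0204 to 0.983 and the high mean from 0.702 to 0.983. Without the 2 patients farthest from the median, r was -0.608 and rho -0.717. Those 2 are among the 4 samples with few values given below, so this does not remove them all. Within the 4 blocks of sample numbers rho was -0.660, -0.700, -0.678 and -0.796 (p = 1e-05 in each), and r was -0.837, -0.191, -0.856 and -0.832. In the block with r of -0.191, leaving out its 2 farthest patients gave -0.460. The 4 samples with a value in under 20% of the regions had means of at least 0.760 over low regions, beyond the 0.452 reached by any patient with a value in at least 50% of the regions.

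**Figure D2:**
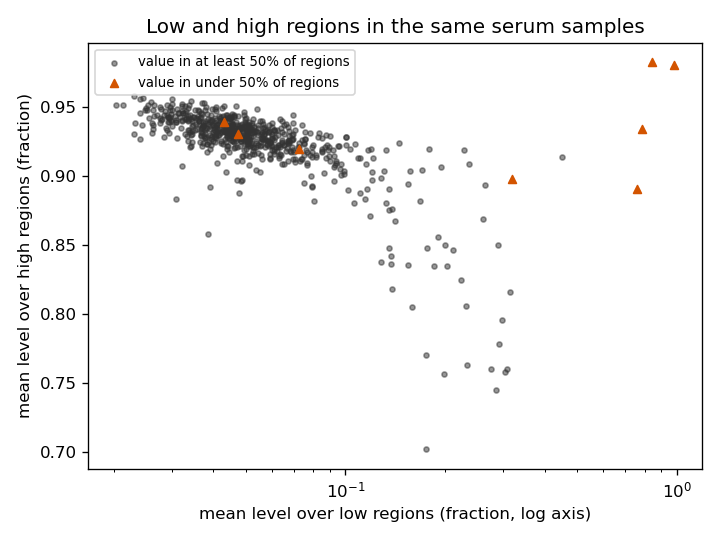
Mean methylation level over low regions (x axis, fraction, log scale) and over high regions (y axis, fraction), 1 point per patient. Triangles mark the 8 patients with a value in under 50% of the regions; among the other points the high mean falls as the low mean rises, with rho -0.701 over all 654 patients.

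Tested region by region, most low regions rose with the mean deviation of the other low regions and most high regions fell. Of the 240 low regions, 74.6% rose, 3 regions fell and 58 did not pass the adjusted threshold. Of the high regions, 65.6% fell, 6 regions rose and 82 did not pass. Among the 52 intermediate regions 23 rose, 17 fell and 12 did not pass. The median rho was 0.225 for low, -0.143 for high and 0.000458 for intermediate regions. Among the regions named above, the strongest rises were those on chromosome 11 at 70.2115 Mb (rho 0.723), chromosome 22 at 50.5241 Mb (0.693), chromosome 19 at 36.2334 Mb (0.646) and chromosome 7 at 45.0667 Mb (0.628). The chromosome 18 region at 61.1439 Mb fell with rho -0.554 and the chromosome 22 region at 45.5977 Mb with rho -0.486. The adjusted p was 2e-05 for all 6. The variable chromosome 2 region at 10.4872 Mb had rho -0.0207 (adjusted p = 0.668).

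**Figure D3:**
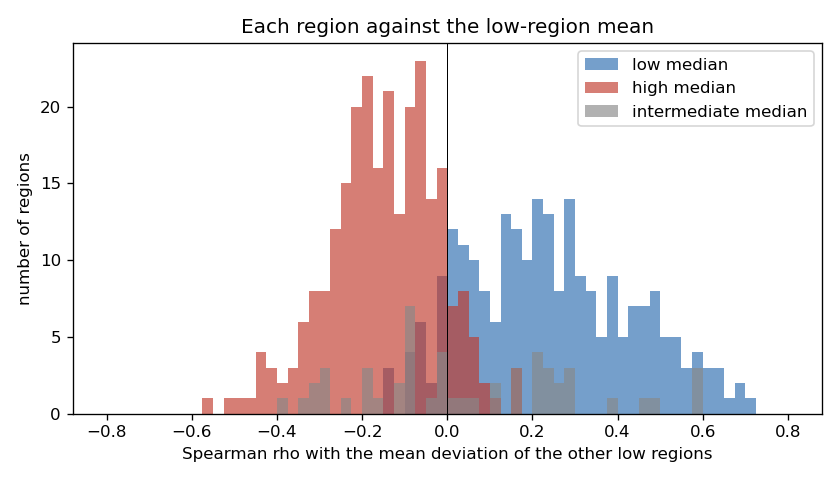
Number of regions (y axis) by the Spearman rho between a region's level and the mean deviation of the other low regions across patients (x axis). Low regions lie mostly to the right of 0 (median 0.225), high regions to the left (median -0.143), and intermediate regions on both sides.

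Neighbouring 100 bp bins varied together, with a much lower mean correlation at larger distances. Pairs of directly neighbouring bins had a mean rho of 0.382, and rho was above 0 in 100% of them. It was above the highest rho of any pair in the shuffles (0.223) in 120 pairs (74.5%). The mean was 0.0478 for 35 pairs at 1 to 100 kb, 0.0186 for 9101 pairs farther apart on a chromosome and 0.0139 for 137853 pairs on different chromosomes. Pairs under 1 kb exceeded pairs on different chromosomes by 0.364 (permutation p = 1e-05), and by 0.359, 0.373, 0.359 and 0.356 within the blocks. With Pearson r the difference was 0.574. Pairs at 1 to 100 kb were not tested against pairs on different chromosomes. A captured region is about 100 bp and reads are 150 bp, so neighbouring bins may be read from the same DNA molecules. Without read data, shared molecules could not be told apart from separate regions that vary together.

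The closest match was between the chromosome 8 regions at 20.3755 and 20.3756 Mb, with rho 0.954. The chromosome 21 regions at 36.4214 and 36.4215 Mb followed with 0.934, those on chromosome 13 at 111.1603 and 111.1604 Mb with 0.926 and those on chromosome 16 at 90.0927 and 90.0928 Mb with 0.922. Neighbours also had similar levels, with a median difference of 0.0192 between their medians. A difference over 0.3 was found in 2 pairs, on chromosome 1 at 161.1689 and 161.1690 Mb (medians 0.938 and 0.583) and on chromosome 7 at 83.4794 and 83.4795 Mb (0.600 and 0.938). Neighbours that varied more between patients matched more closely. Across these pairs, which are not independent replicates, rho between mean SD and correlation was 0.654 (p = 1e-05). The median rho was 0.504 in the 64 pairs with a mean SD of at least 0.1 and 0.264 in the other 97. Of the values in the regions kept, 15.3% were exactly 0 and 8.18% exactly 1. Such ties, and the error of single values, can lower rho where the spread is small. A difference in how closely neighbours are coupled was therefore not shown.

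**Figure D4:**
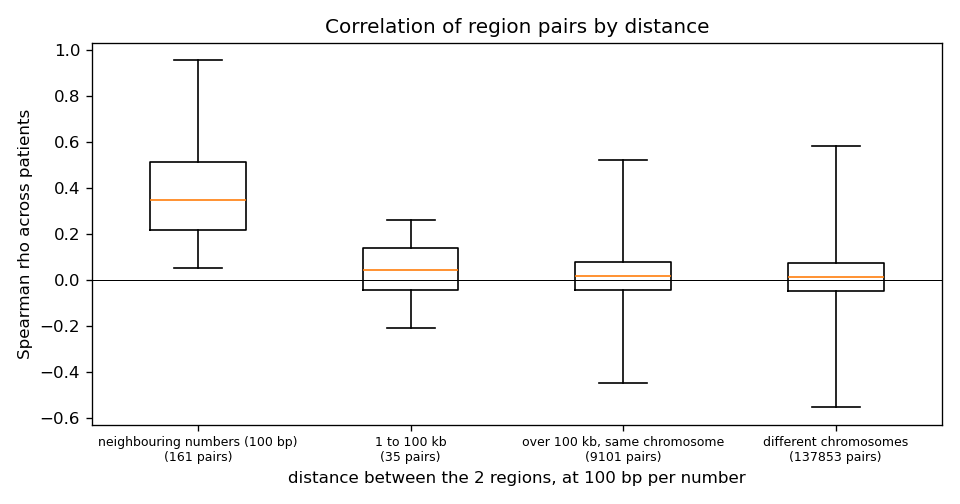
Spearman rho across patients of pairs of regions (y axis) by distance at 100 bp per region number (x axis). Boxes span the quartiles, lines inside them mark the median and whiskers reach the lowest and highest pair; neighbouring regions have a median of 0.349, and the other groups lie close to 0.

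Some regions far apart on the genome also varied together. Of 149878 pairs, 99 had rho of at least 0.5 and 7 had rho of -0.5 or less, while 100 shuffles gave 0 and 0. Of the 99 pairs, 42 lay under 1 kb apart and 57 were over 100 kb apart or on different chromosomes. All 7 negative pairs were distant and joined intermediate regions. Of the 57 distant positive pairs, 36 joined low regions to each other, 10 joined low to intermediate regions and 11 joined intermediate regions. Distant pairs of low regions had a mean rho of 0.0967 and 87.97% were positive. Pairs of high regions had 0.0690 and 86.7%, and pairs of a high and a low region -0.0532 and 24.5%. The 99 positive and 7 negative pairs are 0.0661% and 0.00467% of all pairs. These shares depended on the measure, with 3.02% and 1.17% by Pearson r, and 0.179% and 0.0260% after each patient's mean methylation was regressed out. When the patients were divided at random into equal parts, positive pairs made up 0.107% of all pairs in one part and 0.0607% in the other.

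The 10 named distant pairs, the 5 highest and the 5 lowest in rho, fell into 2 sets of regions. In the first, the low regions on chromosome 11 at 70.2115 Mb, chromosome 21 at 36.4214 Mb and chromosome 22 at 50.5241 Mb rose and fell together. The correlation (Spearman) was 0.582 for chromosomes 11 and 21, 0.579 for 11 and 22, and 0.575 for 21 and 22, with r of 0.736, 0.779 and 0.767. Without 2 patients r was 0.718, 0.763 and 0.746, and within the blocks rho lay between 0.505 and 0.622. In the other set, the chromosome 13 region at 111.1604 Mb rose with the chromosome 8 regions at 20.3756 Mb (rho 0.584, r 0.557) and 20.3755 Mb (rho 0.560, r 0.527). Without 2 patients these r were 0.572 and 0.544, and within the blocks rho lay between 0.463 and 0.654.

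The chromosome 6 region at 16.7296 Mb, with a median level of 0.531, ran against the regions on chromosomes 8 and 13. The correlation (Spearman) was -0.552 with chromosome 8 at 20.3755 Mb, -0.546 at 20.3756 Mb, -0.539 with chromosome 13 at 111.1603 Mb and -0.537 at 111.1604 Mb. It was -0.518 with the chromosome 7 region at 2.1505 Mb. The matching r were -0.548, -0.544, -0.506, -0.513 and -0.488, and without 2 patients -0.547, -0.545, -0.532, -0.524 and -0.487. Within the blocks rho ran from -0.681 to -0.408. All 10 named pairs had a permutation p of 1e-05, over 99.1% to 99.8% of the patients, but they were picked as the extremes of 146954 distant pairs.

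Yield followed the sample numbers, while no such order was detected in the level of methylation. The share of regions with a value had a rank autocorrelation of 0.378 along the numbers (p = 0.0001), and its median was 79.7%, 70.3%, 81.03% and 75.5% in the blocks. The autocorrelation was -0.0258 (p = 0.514) for the low mean and -0.0292 (p = 0.456) for the high mean. Profiles of patients with adjacent numbers correlated at 0.0710 against 0.0649 for all pairs (p = 0.0679). Patients with fewer regions measured had a higher low mean, with rho -0.238 (p = 1e-05, within blocks -0.307 to -0.169). Pearson r was -0.451 (p = 1e-05), and -0.326 without 2 patients. Leaving out 2 patients does not remove all of the 4 samples with a value in under 20% of the regions. For the high mean rho was 0.0628 (p = 0.111) and r -0.0456 (p = 0.239), with r -0.0252 without 2 patients and rho within blocks from -0.0479 to 0.210.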

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

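Removal of samples with a value in under 50% of the regions, the mean deviation from region medians, the blocks for neighbours, the distant pairs, the region-by-region test and the interquartile range were chosen after seeing the data. Of the alternatives computed over 14 results, 89 kept direction and side of the threshold or stayed within 1.5 times the count, 30 moved and 1 turned direction. The median spread of low minus high regions was 0.0165 by SD and -0.0149 by interquartile range, and 0.00579 by SD without samples with a value in under 50% of the regions. The cause was not tested. The opposition of low and high regions lay between rho -0.585 (logit scale) and -0.796 (the fourth block), and the excess for neighbouring regions between 0.356 and 0.574. The first component held 8.99% to 26.3% of the variance. At least 68.8% of the low regions rose with the axis and at least 57.03% of the high regions fell under each alternative run.

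Results that moved are judged on counts and given as shares. With no filter on missing values the classes held 44.4%, 11.03% and 44.6% of 870 regions. Their counts rose since more regions entered, while the shares stayed near 43.8%, 9.49% and 46.7%. Variable regions then made up 41.3%, pairs at 0.5 or more 0.431% and at -0.5 or less 0.318% (0.421% and 0.323% of distant pairs). Pairs with as few as 6 patients in common entered here, and a large rho arises by chance more easily in so few patients. No shuffles were run for them, so these pair shares cannot be set against those of the regions kept. Limits of 0.1 and 0.9 made 20.3% of the regions intermediate. An SD of 0.05 was reached by 77.01% and 0.15 by 10.8%; a scaled median absolute deviation of 0.1 by 13.7%. A rho limit of 0.3 gave 1.03% positive and 0.369% negative pairs (0.987% and 0.376% of distant pairs). Pearson r gave 3.02% and 1.17% (distant 2.95% and 1.15%), and 2.36% and 1.23% (distant 2.28% and 1.21%) without samples with few values. Residuals on mean methylation gave 0.179% and 0.0260% (distant 0.136% and 0.0259%). A random division of the patients into equal parts gave 0.107% positive pairs (distant 0.0755%) in one part and 0.0607% (distant 0.0340%) in the other. Apart from changed limits and the regions and pairs added without the filter, the cause was not tested. Planned results on gene groups and genomic context were not run, since no annotation of hg19 was used here. Read depth is unknown, so a minimum coverage could not be varied.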

Other observations

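The slope test, the choice of regions around chromosome 8 and the samples with few values were chosen after the results were seen. The chromosome 6 region at 16.7296 Mb and the chromosome 8 region at 20.3755 Mb belong to a wider group of regions on several chromosomes. Apart from its direct neighbour at 20.3756 Mb (rho 0.954), 12 regions had an absolute rho of at least 0.4 with the chromosome 8 region, 9 in the same direction and 3 against it. The 9 include chromosome 7 at 2.1505 Mb (rho 0.539), chromosome 12 at 132.2696 Mb (0.506), chromosome 17 at 75.5399 Mb (0.498), chromosome 1 at 116.1937 Mb (0.448) and chromosome 2 at 69.0270 Mb (0.446). Besides the chromosome 6 region, chromosome 10 at 104.4179 Mb (-0.413) and at 14.7018 Mb (-0.406) ran against it. Such a group could be a by-product of the axis of low and high regions. The partial rho of the chromosome 6 and chromosome 8 regions given both class means was -0.543 (bootstrap interval -0.602 to -0.474), against -0.552 without that adjustment, which argues against the axis as its cause. What these regions share was not tested, and no biological explanation was tested, since the labels give a single group.

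Low and high regions moved in opposite directions between patients. An error in conversion or sequencing that raises all low regions alike predicts a slope of 1 for each low region on the others. The 95% interval excluded 1 in 78.3% of the low regions, among patients with a value in at least 50% of the regions. The slopes had a median of 0.689 and an interquartile range of 0.199 to 1.56, with 47.5% of intervals below 1 and 30.8% above it. An error of equal size in all low regions is therefore argued against as the only source. Slopes on levels rest mainly on the patients with the highest means over low regions. They cannot decide whether such an error acts beside other differences or among the remaining patients. The slopes cover low regions only and do not test the fall of the high regions. An error that only raises levels, such as incomplete conversion, would not lower high regions. Yet 65.6% of the high regions fell with the mean deviation of the low regions, 6 regions rose and 82 did not pass. This argues against an error that only raises levels as the only source. Which regions are missing in a patient is argued against by rho -0.699 (-0.749 to -0.645) of mean deviations from region medians. The number of values per patient is argued against by a partial rho of -0.708 (-0.756 to -0.657). That number was little related to the high mean (rho 0.0628), so adjusting for it could change little. It is only a stand-in for yield, and read depth was not tested. An error that differs between regions and can also lower high regions stays open, as does an equal error beside other differences. A varying share of DNA with another methylation pattern, such as tumour DNA, may also give such an axis but was not tested, since no biological grouping is given.

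The 4 samples with a value in under 20% of the regions (11.4% to 13.7%) had high levels in every class. Their means were 0.760 to 0.983 over 55 to 62 low regions, 0.835 to 0.936 over 8 to 13 intermediate regions and 0.891 to 0.983 over 26 to 39 high regions, while the median intermediate mean of all patients was 0.545. Between 63.6% and 100% of their low-region values were at least 0.8. Incomplete bisulfite conversion, or DNA methylated in all regions, predicts an intermediate mean over 0.8 in each, and the lowest was 0.835. Either may be the source, but this result could hardly have differed, so no conclusion is drawn from it. The low and high means of these samples were already at least 0.760 and 0.891. Their high means, 0.891 to 0.983, lay on both sides of the 0.930 of the median patient, over fewer regions. The 0.545 is taken over all intermediate regions with a value and not over the same regions. These values do not separate the 2 sources or exclude others, and no biological explanation was tested.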
